A study of Mus musculus with 3 samples.

How the data were processed

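Total RNA-seq after ribosomal RNA depletion was measured in the cytosolic fraction of mouse bone marrow-derived macrophages, per the labels. The 3 libraries form 1 group, with replicate numbers taken from the labels, which call them biological replicates of separate biosamples with the same donor identifier. The labels do not say whether they came from separate animals, so tests over libraries measure only the spread between these libraries, which may be technical.

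Per the deposited README, the gene and transcript tables derive from alignments to the mouse assembly mm10 with annotation M21, and a further transcript table was made directly from the reads. The aligner and quantifier are not given in the sources used here. The deposited expected counts are estimated reads per gene, with reads shared between genes split, so near-identical copies are uncertain. The deposited TPM values are transcript abundances normalised for length and for the total over all rows of a table, and the deposited FPKM values are fragments relative to gene length and library total, both by the authors, per the file headers. Coordinates are those of GENCODE M21 on GRCm38, and all 55536 gene identifiers of the tables were found there.

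The gene table held 81881 rows, of which 26248 numeric tRNA rows, 96 ERCC rows and 1 phiX row name no gene and were left out of library sizes and tests. They took 0.418%, 0.248% and 0.165% of expected counts in replicates 1, 2 and 3. Gene rows held 28981178, 53119941 and 46783133 expected counts. A count of 0 allows 0.104, 0.0565 and 0.0641 CPM, from 3 counts of the total. Intervals are 95% Wilson intervals, and they and these limits cover counting error only.

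Levels are deposited TPM, and lists were compared on log2(TPM + 1), a pseudocount of 1 that understates differences among low genes. The 9 contrasts used two-sided permutation tests over genes with 100000 resamples, or exact ones where a list held fewer than 10 members, genes shared by both lists left out, and Benjamini-Hochberg adjustment over the contrasts. Genes are not independent replicates, so each p describes the lists in these libraries. Expected counts were rounded and scaled with TMM in edgeR 4.0.16 (R 4.3.3), which also gave the dispersion over genes with 10 or more counts in every library. Differences between libraries used a chi-square test of homogeneity on genes with a mean of 10 or more rounded counts, Benjamini-Hochberg 0.05 and a ratio of at least 2, with 0.5 counts added for ratios. Fisher's exact test was used for lists. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

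On simulated Poisson counts for the 13636 genes tested between libraries, the chi-square criteria recovered 94.0% of genes changed 4-fold and 1.0% of those changed 1.5-fold, and called 1 unchanged gene. Those counts held counting noise alone, so this says nothing of the spread between libraries. Negative binomial counts of unchanged genes with the common coefficient of variation of 0.210 were therefore simulated 20 times, and the criteria called 1096 genes on average. Protein-coding genes were also simulated 20 times with their own coefficient of 0.170, which gave 305 calls on average. For the list contrasts, 5.0% of 200 simulated pairs of equal lists of 24 members and 92.0% of pairs 2 log2 units apart had p under 0.05.

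The 27 gene lists, the contrasts, the tests and the rule for named genes were fixed before the data were examined. The rule takes the 3 highest genes of each list, the 6 highest and 3 lowest of the cytokine, negative regulator, antimicrobial, interferon, alternative activation and immediate early lists, the 10 most abundant genes outside mitochondrial, ribosomal RNA, tRNA and spike-in entries, the 10 largest ratios between libraries among genes differing at a mean of 10 TPM or more, the 6 most abundant genes whose leading transcript differs (1 of them is not reported here), Tlr4 and Malat1. Il6, Kcnq1ot1, Firre and Airn fall outside it and were named after their values were seen, as were the genes of 5 further lists under the other observations. Of 410 listed symbols, 1 was matched through a synonym, and for 1 symbol with several identifiers, Aldoa, the identifier with more counts was used.

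Alternatives were other TPM thresholds and pseudocounts, FPKM, posterior mean TPM, read-derived values, medians over members, members at 1 TPM or more, DESeq2 1.42.0 size factors, other count filters and ratios, and each replicate left out. TPM rescaled to protein-coding genes, protein-coding genes only, list enrichment with each replicate left out, and list enrichment against genes of the same class (protein-coding or not) were chosen after seeing the data.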

Results

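Cytosolic RNA was profiled in bone marrow-derived macrophages, which are primary phagocytes grown from marrow, of C57BL/6J mice. Per the labels, the cells received lipid A at 100 ng/ml for 12 h, were kept for another 12 h after its removal, and were collected at 0 min of a second stimulation. Lipid A is the membrane anchor of bacterial lipopolysaccharide and the ligand sensed by the receptor Tlr4. The series held 1 group of 3 libraries, numbered as biological replicates 1, 2 and 3, all under the same donor identifier. No untreated or restimulated group was analysed here, so the values describe the state of these cells and no effect of lipid A. Depth was 28981178, 53119941 and 46783133 expected counts on genes in replicates 1, 2 and 3. Values below are in TPM (transcript abundance normalised for length and library total, as deposited), as mean ± SD over the 3 libraries.

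Small non-coding RNAs took most of the TPM, and the ferritin genes, Saa3 and Ccl5 gave the most abundant messenger RNAs. The 7SL genes Rn7s1 and Rn7s2, which encode the RNA of the signal recognition particle, held 290805 ± 32270 and 291545 ± 32812 TPM (SD, n = 3). Rn7sk, Rpph1 and Rmrp, other small RNAs made by RNA polymerase III, held 46694 ± 17179, 38521 ± 8054 and 12248 ± 6893 TPM (SD, n = 3), the last under 1 of 2 overlapping Rmrp entries, whose other entry held 4535 ± 1576 TPM. The split of reads between the near-identical 7SL copies, and between the Rmrp entries, is uncertain. Among messenger RNAs the ferritin subunit genes led, with Fth1 at 16917 ± 241 and Ftl1 at 7742 ± 876 TPM, followed by Saa3 at 5389 ± 2549 and Ccl5 at 4852 ± 869 TPM (SD, n = 3). In all, 9523 genes reached 1 TPM in every library, of which 9074 were protein-coding, and 399 reached 100 TPM. At a threshold of 5 TPM the number was 5922.

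Rn7s1 and Rn7s2 together took 58.2 ± 6.51% of TPM but 7.89 ± 2.32% of expected counts (SD, n = 3). Protein-coding genes took 88.7 ± 1.80% of expected counts and 29.9 ± 2.35% of TPM. Mitochondrially encoded genes held 0.224% of counts in replicate 1 (Wilson 95% interval 0.222 to 0.226%), 0.219% in replicate 2 (0.218 to 0.220%) and 0.513% in replicate 3 (0.511 to 0.515%). Ribosomal protein genes held 1.17 ± 0.136% of counts, and the 10 most abundant genes 12.9 ± 2.30% (SD, n = 3). The 10 most abundant genes took 71.9% of TPM. Every TPM value here therefore depends on the 7SL share. With TPM rescaled to protein-coding genes, chosen after seeing the data, the list medians given below became 467 TPM for interferon-stimulated genes and 10.2 TPM for cytokines, and 11076 genes reached 1 TPM in every library. With read-derived TPM 7781 did. The intervals cover counting error only.

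Interferon-stimulated genes, which are switched on by interferons, were mostly held at high levels, whereas inflammatory cytokines and mediators ranged from very abundant to nearly absent. Of the 32 interferon-stimulated genes, 31 reached 10 TPM in every library, Cxcl9 being the exception. All 32 interferon-stimulated genes reached 1 TPM in every library, with a list median of 140.3 ± 24.97 TPM (SD, n = 3). The antiviral genes Ifit2 and Rsad2 stood at 964 ± 290 and 863 ± 251 TPM, the transcription factor gene Irf7 at 738 ± 207, and Bst2, Ifit3 and Isg15 at 655 ± 106, 645 ± 161 and 630 ± 138 TPM. The lowest members were Mx2 (22.1 ± 4.85 TPM), Oas2 (20.6 ± 7.28) and the chemokine gene Cxcl9 (3.59 ± 1.88). Of the 24 cytokines and mediators, 15 reached 1 TPM in every library, and the list median was 3.02 ± 0.548 TPM. Ccl5 (chromosome 11, 83525778 to 83530518, minus strand) led that list at 4852 ± 869 TPM, followed by Cxcl10 (chromosome 5, 92346638 to 92348889, minus strand) at 412 ± 217. Both encode chemokines that draw T cells. The chemokine genes Ccl3, Ccl4, Ccl7 and Ccl2 held 198 ± 44.2, 178 ± 57.9, 123 ± 27.6 and 107 ± 30.8 TPM, while Csf3, Il12a and Lif held 0.040 ± 0.010, 0.017 ± 0.021 and 0.010 ± 0.010 TPM. Il6, a fever-inducing cytokine gene, held 0.787 ± 0.649 TPM. The mean log2(TPM + 1) was 7.21 for the interferon-stimulated genes and 3.24 for the cytokines, a difference of 3.97 (two-sided permutation test over genes, p = 1e-05, adjusted p = 3e-05 over 9 contrasts). That p is the smallest the permutations can give. Within libraries the difference was 3.97 ± 0.45 (SD, n = 3), positive in 3 of 3, with an exact sign-flip p of 0.25, the smallest that 3 libraries allow. With both lists restricted to members at a mean of 1 TPM or more, the difference was 2.23 (permutation test over genes, adjusted p = 0.00816).

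**Figure D1:**
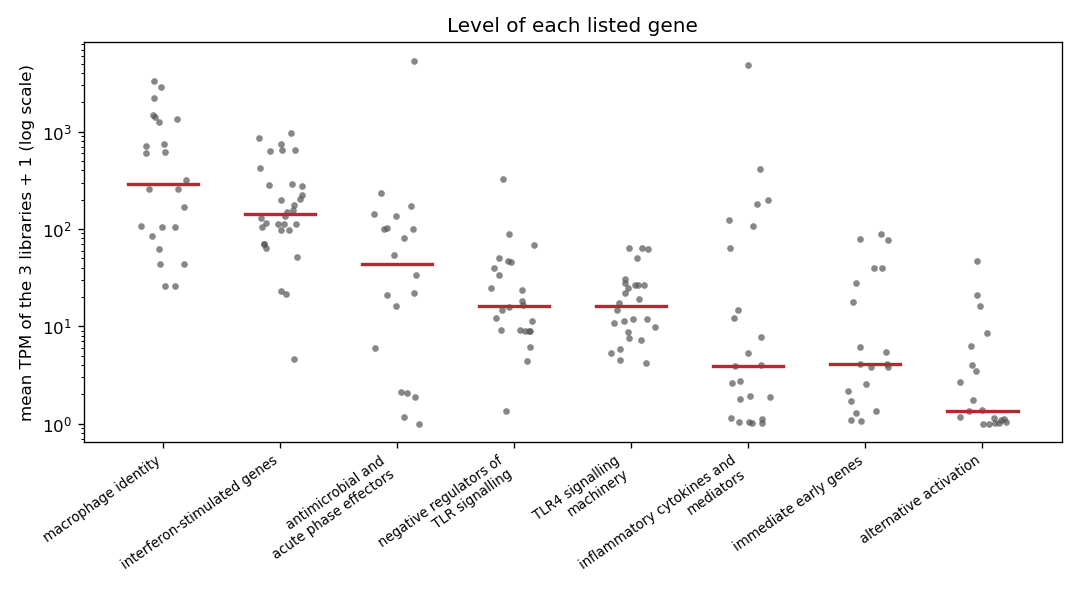
Each point is 1 gene of a list, placed by its mean TPM over the 3 libraries plus 1 on a log axis; red bars mark the list medians. Most interferon-stimulated genes lie together at high levels, with Cxcl9 apart at 3.59 TPM, and the cytokine list stretches from Ccl5 at 4852 TPM down to Lif at 0.010 TPM.

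Negative regulators of Toll-like receptor signalling were present in nearly full number but at moderate levels. Of 24 genes, 23 reached 1 TPM in every library, with a list median of 15.2 ± 1.74 TPM (SD, n = 3). Acod1, the enzyme that makes itaconate, led at 324 ± 52.4 TPM, followed by the transcriptional repressor gene Atf3 at 88.2 ± 19.5, the NF-κB inhibitor gene Nfkbia at 67.8 ± 8.97, Inpp5d at 49.5 ± 13.0, Tnip3 at 45.4 ± 7.85 and the interleukin-1 receptor antagonist gene Il1rn at 45.0 ± 13.2 TPM. Dusp1, Socs1 and Sigirr were lowest, at 5.14 ± 0.897, 3.40 ± 0.991 and 0.337 ± 0.170 TPM. The list lay 0.97 above the cytokines in mean log2(TPM + 1), which did not pass the test (permutation p = 0.217, adjusted p = 0.279). The median over members gave 2.06, past the threshold, and restricting both lists to members at a mean of 1 TPM or more turned the sign, to -0.60.

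Antimicrobial and acute phase effectors were dominated by Saa3, an acute phase apolipoprotein gene (chromosome 7, 46711998 to 46715700, minus strand), at 5389 ± 2549 TPM. Cybb and Ncf1, subunits of the phagocyte NADPH oxidase, held 232 ± 17.0 and 135 ± 11.8 TPM. Slc11a1, a phagosomal metal transporter gene, held 172 ± 29.7 TPM, the scavenger receptor gene Marco 141 ± 77.1 and the complement gene Cfb 102 ± 36.6 TPM (SD, n = 3). Slpi and Camp held 0.867 ± 0.290 and 0.167 ± 0.021 TPM. Ptx3 had 0 counts in every library, which allows up to 0.104, 0.0565 and 0.0641 CPM (expected counts relative to the library total) in replicates 1, 2 and 3. Of 20 genes, 16 reached 1 TPM in every library, with a list median of 43.1 ± 2.12 TPM. The list lay 1.61 above the cytokines in mean log2(TPM + 1), which did not pass the test (permutation p = 0.112, adjusted p = 0.168).

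The TLR4 signalling machinery was expressed in full, and immediate early genes were lower. All 26 signalling genes reached 1 TPM in every library, with a list median of 14.8 ± 0.905 TPM (SD, n = 3). Tlr4 itself (chromosome 4, 66827584 to 66930284, plus strand) held 25.6 ± 3.66 TPM, and the kinase gene Ikbke, the transcription factor gene Irf5 and the co-receptor gene Cd14 were highest, at 63.4 ± 21.7, 63.3 ± 4.99 and 62.1 ± 15.1 TPM. Against the cytokines the difference of 0.77 in mean log2(TPM + 1) did not pass the test (permutation p = 0.288, adjusted p = 0.324). The median over members gave 2.05, past the threshold, and members at a mean of 1 TPM or more gave -0.98.

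Of 20 immediate early genes, which respond within minutes to stimulation, 13 reached 1 TPM in every library, and the list median was 3.48 ± 0.415 TPM (SD, n = 3). Atf3, Klf6 and Gadd45b were highest, at 88.2 ± 19.5, 78.4 ± 10.01 and 76.7 ± 16.1 TPM, followed by Zfp36 at 39.0 ± 5.92, Junb at 38.6 ± 2.72 and Jun at 26.9 ± 2.27. Nr4a1, Egr3 and Fosb held 0.290 ± 0.219, 0.10 ± 0.044 and 0.063 ± 0.057 TPM. The list lay below the TLR4 machinery by a difference of -1.22 in mean log2(TPM + 1) (permutation p = 0.0214, adjusted p = 0.0385), negative in 3 of 3 libraries. This call was lost with read-derived TPM (-0.93) and with members at a mean of 1 TPM or more (-0.41).

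Macrophage identity genes were uniformly high, and markers of alternative activation and of other cell types were mostly close to 0. All 24 identity genes reached 10 TPM in every library, led by the lysozyme gene Lyz2 at 3326 ± 193 TPM and the cathepsin genes Ctsd and Ctsb at 2895 ± 278 and 2218 ± 210 TPM (SD, n = 3). Of 20 alternative activation genes, 8 reached 1 TPM in every library. The interleukin-4 receptor gene Il4ra held 46.4 ± 15.0 TPM, the mannose receptor gene Mrc1 19.8 ± 3.34, Tgm2 15.3 ± 3.53, Vegfa 7.50 ± 0.880, Folr2 5.29 ± 0.316 and Clec10a 3.03 ± 0.597 TPM. Arg1 held 0.013 ± 0.012 TPM, and Retnla and Ccl17 had 0 counts in every library. Identity genes lay 6.87 above alternative activation genes in mean log2(TPM + 1) (permutation p = 1e-05, adjusted p = 3e-05), at 6.87 ± 0.12 within libraries (SD, n = 3).

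Of the 77 markers of other cell types, 9 reached 1 TPM in every library and 16 had 0 counts. The 9 were 4 of 13 neutrophil markers and 1 each of 10 dendritic cell, 8 B cell, 10 T and NK cell, 5 platelet and 5 endothelial markers. None of 7 mast cell and basophil, 10 fibroblast and stromal or 9 erythroid markers reached 1 TPM. The exceptions with the highest levels were the platelet factor gene Pf4 at 74.1 ± 15.9 TPM, the granulocyte colony-stimulating factor receptor gene Csf3r at 35.6 ± 10.2, Cd4 at 18.1 ± 0.684 and the endothelial receptor gene Kdr at 5.62 ± 3.00 TPM (SD, n = 3). S100a9 and S100a8, abundant in neutrophils, held 4.54 ± 1.70 and 2.96 ± 0.813 TPM. Batf3, a dendritic cell gene, held 2.16 ± 0.894 TPM and Cd79b, of B cells, 1.62 ± 0.747 TPM. Kit of mast cells held 0.257 ± 0.145, Thy1 of stromal cells 0.143 ± 0.10 and Epor of erythroid cells 0.420 ± 0.404 TPM, the last being 0.19 without replicate 3. Of 9 osteoclast markers, 3 reached 1 TPM in every library, led by Acp5 at 13.2 ± 3.95 TPM. Identity genes lay 7.79 above the other markers in mean log2(TPM + 1) (permutation p = 1e-05, adjusted p = 3e-05). The lists were picked as genes of macrophages and of other cells, so in a macrophage culture such a gap was built into their choice.

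Genes of both arms of central carbon metabolism were expressed in full, with list medians of 64.2 ± 6.56 TPM for glycolysis and 33.0 ± 3.91 TPM for the TCA cycle and respiratory chain (SD, n = 3). All 17 glycolysis genes reached 1 TPM in every library, led by Gapdh, Aldoa and Pkm at 352 ± 52.9, 171 ± 24.7 and 165 ± 25.7 TPM (SD, n = 3). All 19 genes of the TCA cycle and respiratory chain did so too, led by Atp5b, Cox4i1 and Cox5a at 257 ± 10.7, 190 ± 8.42 and 162 ± 23.8 TPM. The difference of 0.19 in mean log2(TPM + 1) did not pass the test (permutation p = 0.754, adjusted p = 0.754), which does not show that the levels are alike, and the median over members gave 0.97, also not past the threshold. Among the other lists, all 14 antigen presentation genes reached 1 TPM, led by B2m, H2-K1 and H2-D1 at 3362 ± 554, 2363 ± 337 and 1763 ± 222 TPM. All 17 translation genes did so, led by Eef1a1 at 871 ± 76.1 TPM. So did 8 of 10 oxidative stress genes, led by Prdx1 and Sqstm1 at 333 ± 73.0 and 234 ± 76.0 TPM, and 12 of 13 sterol and LXR genes, led by Scd2 and Abcg1 at 83.4 ± 28.4 and 78.3 ± 15.9 TPM. Of 23 cell cycle genes, 11 reached 1 TPM, with Pcna highest at 64.3 ± 2.51 TPM and a list median of 1.26 ± 0.527 TPM. Of 11 replication-dependent histone genes, 10 did, led by Hist1h2bc at 61.1 ± 15.4 TPM.

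Nuclear-retained RNAs were on average lower than macrophage identity genes, but replicate 3 held far more of several of these RNAs. Of 10 RNAs, 4 reached 1 TPM in every library and 3 had 0 counts. Malat1 (chromosome 19, 5795690 to 5802672, minus strand) held 158, 91.0 and 1343 TPM in replicates 1, 2 and 3. Neat1, the RNA scaffold of paraspeckles, held 16.8, 10.4 and 91.4 TPM. Rn7sk was high in all 3 libraries, at 51085, 27745 and 61251 TPM. The list differed from the identity genes by -4.74 in mean log2(TPM + 1) (permutation p = 0.0005, adjusted p = 0.00112), and by -4.96, -5.07 and -4.21 in replicates 1, 2 and 3. With members at a mean of 1 TPM or more the call was lost (-2.45). The identity list was picked as genes that macrophages express, and no nuclear fraction was compared. The contrast therefore does not measure depletion of these RNAs from the cytosol.

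**Figure D2:**
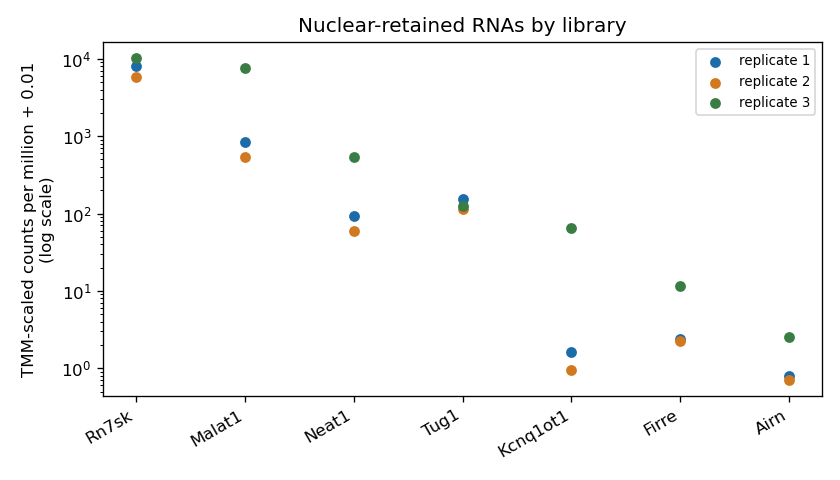
TMM-scaled CPM plus 0.01, on a log axis, of each nuclear-retained RNA tested, with 1 point per library. Replicate 3 lies highest for 6 of the 7 RNAs, with Malat1 at 7529 CPM against 841 and 538 in replicates 1 and 2.

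Of the genes that differed between libraries, most were not protein-coding and most were highest in replicate 3. The common biological coefficient of variation from edgeR was 0.210 over 12090 genes, and 0.169 without replicate 3. Of 13636 genes tested, 2219 differed between libraries (chi-square test of homogeneity with Benjamini-Hochberg adjustment, ratio of highest to lowest library of at least 2), and 1596 of these were highest in replicate 3. Without replicate 3 the number was 605. Protein-coding genes made up 946 of the 2219, and 1125 of the 1273 other genes that differed were highest in replicate 3. This test compares these libraries and no conditions, covers counting error only and treats reads as independent molecules, so 10180 genes (74.7%) passed it at any ratio. In 20 simulations of unchanged genes, chosen after seeing the data, the common coefficient of variation of those 12090 genes was used. The same criteria called 258 genes that are not protein-coding on average (228 to 296), against 1273 in the libraries. They called 839 protein-coding genes (772 to 900), against 946. With the coefficient of protein-coding genes alone, 0.170, they called 305 protein-coding genes (283 to 335). Both coefficients were estimated from the differences they are set against, and no single gene or list was tested against this spread. No coefficient was estimated for genes that are not protein-coding alone. The gap between 258 and 1273 therefore does not show an excess over their own spread. No pair of libraries agreed within counting error, with 611 to 2043 genes differing per pair, so no pair was counted as 1 library deposited again. That does not show that the libraries came from separate cultures or animals.

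Among genes at a mean of 10 TPM or more, the largest ratios belonged to short or non-coding models. Gm26917 held 86.6, 52.8 and 6489 TMM-scaled CPM in replicates 1, 2 and 3, and its neighbour Gm42418 held 85.8, 37.8 and 912. CT010467.1, annotated as ribosomal RNA, overlaps Gm42418 on the opposite strand of chromosome 17. CT010467.1 held 616, 27.1 and 282, but was highest in replicate 3 by TPM, at 374 against 227 and 12.2. Whether the counting used strand is not given in the sources used here, so these values are uncertain. The libraries were depleted of ribosomal RNA, and uneven leftover ribosomal RNA was not tested as a source of these differences. Snora73b, a small nucleolar RNA, held 0.213, 0.338 and 5.46, and Gm22988 and Gm26448 were also highest in replicate 3, while Gm14303 was highest in replicate 1. Gm23472, Gm23444 and Gm24497 had 0 counts in 1 library each. Gm23472 and Gm23444 carried equal values in every library, so the split of reads among these copies is uncertain.

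By list, replicate 3 stood out in nuclear-retained RNAs, replicate 2 in oxidative stress genes and replicate 1 in interferon-stimulated genes. Nuclear-retained RNAs were 5.19-fold higher in replicate 3 than in the other libraries (mean log2 2.37, SE 0.73 over 7 RNAs), and 5 of 7 differed (5 when adjusted over the list alone). They include Malat1 and Neat1, and also Kcnq1ot1, Firre and Airn. This was the only list of 27 enriched among all differing genes (Fisher's exact test, odds ratio 12.9, adjusted p = 0.0482). None of the 7 is protein-coding, and 60.7% of the 2096 such genes tested differed, against 8.20% of protein-coding genes. Against genes of the same class, a background chosen after seeing the data, the enrichment was not called (odds ratio 1.62, adjusted p = 0.842). On that background 5 other lists were: cytokines and mediators (odds ratio 7.17, adjusted p = 0.00878), oxidative stress genes (11.3, 0.00878), antimicrobial effectors (5.63, 0.0211), immediate early genes (4.82, 0.0287) and cell cycle genes (3.97, 0.0484). Among all genes tested but without replicate 3, nuclear-retained RNAs were not called either, and 4 other lists were: immediate early genes, oxidative stress genes, cytokines and mediators, and cell cycle genes. With a ratio of at least 1.5, 5 lists were called: cytokines and mediators (17 of 18 genes, odds ratio 45.9, adjusted p = 8.14e-08), oxidative stress genes (9 of 10, 24.3, 0.000803), interferon-stimulated genes (19 of 32, 3.94, 0.00147), nuclear-retained RNAs (6 of 7, 16.2, 0.0144) and, depleted, the TCA cycle and respiratory chain (0 of 19, adjusted p = 0.019).

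Interferon-stimulated genes were highest in replicate 1 for 31 of 32 members, by a mean log2 of 0.55 (SE 0.04) over the other libraries, above 100% of 10000 random lists matched on expression. The random lists were drawn from all genes tested, and many that are not protein-coding were lower in replicate 1. For lists of low genes, the percentiles below can therefore reflect gene class. Random lists hold genes drawn separately, whereas genes of 1 list may vary together. Translation genes in replicate 2, at a mean log2 of only 0.21, also lay above 100% of random lists. A high percentile therefore does not show a larger shift than other lists of co-varying genes have. The percentiles and SEs treat genes as independent and were not adjusted for the number of lists and libraries scanned. Only Cxcl9 passed the 2-fold criterion (1 gene when adjusted over the list alone), against 19 of 32 at a ratio of 1.5. Endothelial markers were also highest in replicate 1 for 3 of 3 tested (mean log2 0.96, SE 0.18, above 99.7% of random lists), and 2 differed (2 when adjusted over the list alone), Kdr at 87.7, 44.3 and 29.4 and Pecam1 at 6.07, 2.57 and 3.90 TMM-scaled CPM in replicates 1, 2 and 3. Dendritic cell markers were highest there for 4 of 7 (mean log2 0.29, SE 0.29, above 98.5% of random lists), and 2 differed (2 when adjusted over the list alone). Neutrophil markers were lowest there for 6 of 7 (mean log2 -0.92, SE 0.37, above 5.59% of random lists), and 2 differed (2 when adjusted over the list alone). Antigen presentation genes were highest in replicate 1 for 12 of 14 (mean log2 0.28, SE 0.05) and negative regulators for 14 of 24 (mean log2 0.25, SE 0.07), above 99.5% and 99.8% of random lists. Cytokines and mediators were lowest in replicate 3 for 14 of 18 members (mean log2 -0.73, SE 0.14) and highest in replicate 2 for 9 (mean log2 0.63, SE 0.17, above 100% of random lists), and 7 of 18 differed (7 when adjusted over the list alone), among them Cxcl10, highest in replicate 1, at 959, 476 and 350 and Ccl2 at 120, 134 and 62.2 TMM-scaled CPM in replicates 1, 2 and 3. All 10 oxidative stress genes were highest in replicate 2 (mean log2 0.99, SE 0.19), and 5 differed (5 when adjusted over the list alone), with Sqstm1, a selective autophagy receptor gene, at 597, 1067 and 502. Immediate early genes were highest in replicate 2 for 12 of 20 (mean log2 0.56, SE 0.20), and 6 differed (7 when adjusted over the list alone). In replicate 1 their mean log2 was -0.65 (SE 0.32), with 10 genes lowest but 8 highest there. Cell cycle genes were lowest in replicate 1 for 19 of 23 (mean log2 -0.54, SE 0.08). Of the antimicrobial effectors, 6 of 18 differed (6 when adjusted over the list alone), with Saa3 at 3722, 1483 and 3228 and Marco at 217, 351 and 551 TMM-scaled CPM. Of the other lists, 6 of 23 cell cycle genes, 2 of 24 negative regulators, 2 of 15 alternative activation genes, 2 of 13 sterol and LXR genes, 2 of 11 histone genes and 1 of 24 macrophage identity genes differed, with the same numbers when adjusted over the list alone. No gene of the TLR4 machinery, glycolysis, TCA cycle and respiratory chain, antigen presentation or translation lists passed the 2-fold criterion. The cell type marker lists had 1 to 7 genes each in this test, and none was called on either background.

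**Figure D3:**
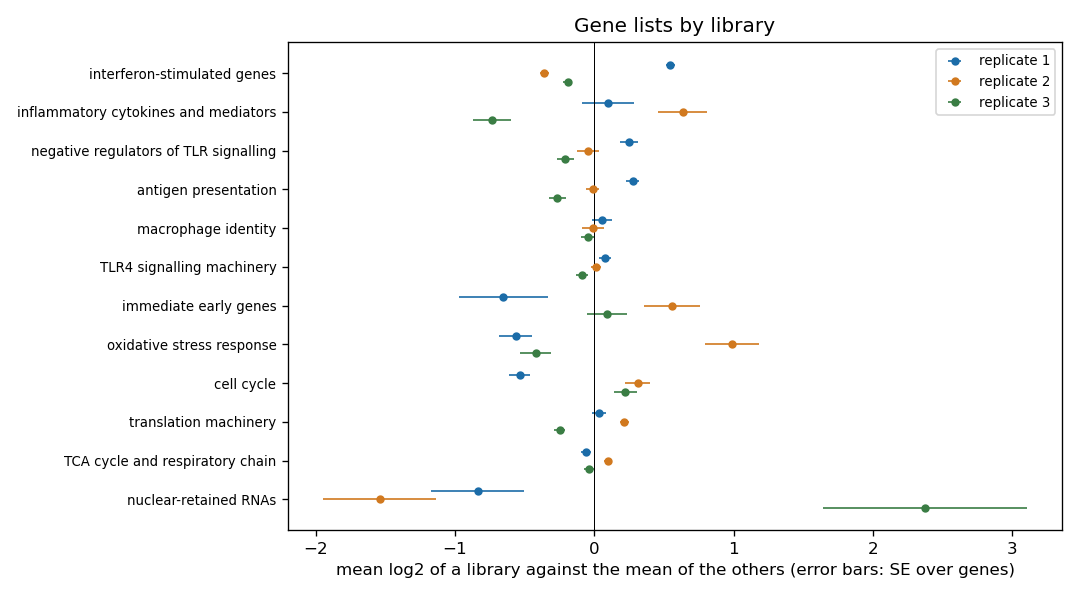
Each point is the mean log2 of a list in 1 library against the mean of the other libraries, with bars for the SE over genes. Interferon-stimulated genes are highest in replicate 1 (0.55), oxidative stress genes in replicate 2 (0.99) and nuclear-retained RNAs in replicate 3 (2.37).

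The alignment-derived and read-derived quantifications ranked the 10556 genes compared much alike, but split the TPM total differently. Protein-coding genes held 29.9 ± 2.35% of alignment-derived TPM and 11.8 ± 2.87% of read-derived TPM (SD, n = 3). Gm12895 and Gm12896 held 203160 and 203187 read-derived TPM but 0 counts in the alignment tables. Across 10556 genes, Pearson's r of log2(TPM + 1) was 0.970 ± 0.004 and Spearman's rho 0.970 ± 0.004 (SD, n = 3 libraries). Genes are not independent replicates, so no p is given. The leading transcript differed for 354 of 3927 genes with several transcripts and a mean of 10 or more TPM, 9.01%, for 548 genes at 5 or more TPM and 72 at 50 or more, and for 12 when the leading transcript had to hold over 0.6 of its gene in both tables. For H2-K1 the alignment table put 44.2 ± 0.623% on the retained-intron transcript H2-K1-215 and 41.4 ± 0.749% on the protein-coding H2-K1-201. The read-derived quantification put 35.3 ± 3.03% and 49.9 ± 2.48% on them (SD, n = 3). For Aif1 the retained-intron Aif1-205 and the protein-coding Aif1-203 held 51.4 ± 2.89% and 48.1 ± 2.78% in the first. In the second they held 40.9 ± 0.941% and 58.3 ± 0.719%. Rpl10, Rpl13a and the long non-coding RNA AW112010 also had different leading transcripts. Rpl10-201 held 81.5 ± 2.64% of its gene in the first and 21.6 ± 2.70% in the second.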

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

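All tests for the interferon-stimulated genes, a pattern first stated as a lower level in replicate 2 and restated for replicate 1, were chosen only after the result was seen. No biological explanation was tested for either pattern weighed here, since the series has 1 group.

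Replicate 3 held more of the long nuclear-retained RNAs, with Malat1, Neat1 and Kcnq1ot1 at 8.95, 5.71 and 40.9 times the higher of the other libraries. All tested snRNA, snoRNA and scaRNA genes (22, 21 and 5) were also highest there, and mitochondrially encoded genes held 0.513% of counts in replicate 3 against 0.224% and 0.219% in replicates 1 and 2, which was not tested as a sign of another fraction or RNA quality. Genomic DNA as the source of all the added Kcnq1ot1 reads is argued against. Together, 1466 olfactory and vomeronasal receptor genes held 3672 expected counts in replicate 3, 3.06% of the 119924 that those reads per kilobase would predict. They held 2006 and 2647 in replicates 1 and 2, and a smaller share of genomic DNA in replicate 3 is not excluded. Nuclear RNA carried into the cytosolic fraction stays open beside a difference in fraction or RNA quality. As predicted for nuclear RNA, the retained-intron share was highest in replicate 3 for 88.7% of 4955 genes (Wilson 95% interval 87.8 to 89.6%). Reads from genomic DNA could raise that share too, so it does not separate the 2 sources. The median share was 0.617%, 0.510% and 3.86% in replicates 1, 2 and 3.

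Replicate 1 held more of the interferon-stimulated genes, 31 of 32 being highest there. Scaling of the library is argued against by a log2 gap of 0.61 (SE 0.05) to the TCA cycle and respiratory chain genes. A larger share of macrophages is argued against by a gap of 0.49 (SE 0.08) to the macrophage identity genes. GC content and transcript length are argued against, since none of 10000 matched random lists lay as high (highest log2 0.41 against 0.55), a share of 0.01% with the list itself counted, the smallest this test can give. That share bears on GC content and length alone, since genes of the list may vary together. Endothelial markers (log2 0.96, SE 0.18, 3 genes), antigen presentation genes (0.28, SE 0.05) and negative regulators (0.25, SE 0.07) were also higher in replicate 1. Lists lower there included neutrophil markers (-0.92, SE 0.37, 7 genes), immediate early genes (-0.65, SE 0.32), oxidative stress genes (-0.57, SE 0.12) and cell cycle genes (-0.54, SE 0.08). Neither other cells nor differences in culture or washout were tested as explanations, so these stay open.

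Signal outside the main measurement appeared in 3 places, each above the limit that a count of 0 allows. The phiX174 row held 0.277 ± 0.129% of expected counts (SD, n = 3). In the read-derived tables, the processed pseudogenes Gm12895 and Gm12896 on chromosome 4 held 9.28 ± 5.25% of counts, with 4.91%, 7.81% and 15.1% in replicates 1, 2 and 3. The miRNA models Gm24245, Gm24270 and Gm23935, of 57 bases each, held 1.72 ± 0.228%. By read-derived TPM, Gm12895 and Gm12896 held 203160 ± 61817 and 203187 ± 61798, and each of these miRNA models 85146 ± 9387 (SD, n = 3). All 5 models had 0 expected counts in the alignment tables.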

How the results depend on the processing

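Of 81 alternative settings over the 9 level contrasts, 74 kept direction and side of the threshold, and the contrasts of interferon-stimulated genes with cytokines and of macrophage identity with alternative activation and with other cell type markers did so under every setting run. The difference between interferon-stimulated genes and cytokines shrank to 2.23 with members at a mean of 1 TPM or more. With members at a mean of 1 TPM or more, negative regulators and TLR4 machinery against cytokines reversed to -0.60 and -0.98, and immediate early genes against TLR4 machinery (-0.41) and nuclear-retained RNAs against identity genes (-2.45) lost their calls, with fewer genes tested. The median over members brought negative regulators (2.06) and TLR4 machinery (2.05) past the threshold, and read-derived TPM took immediate early genes (-0.93) below it. Pseudogene and miRNA models without alignment counts took much of the read-derived TPM total, which lowers all other genes in read-derived TPM. Whether this caused the lost call was not tested, nor was the cause of the other shifts. A 5 TPM threshold left 5922 detected genes, by construction.

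The coefficient of variation was 0.437 without a count filter, 0.162 with 100 or more counts, 0.293 with read-derived counts, and 0.169 to 0.242 with a replicate left out. Genes differing numbered 3997, 486 and 5499 under those 3 settings, 3697 at a ratio of 1.5, 947 for protein-coding genes only (chosen after seeing the data), and 605 to 2046 with a replicate left out, lowest without replicate 3. Lists called numbered 5 at a ratio of 1.5 (1 of them depleted), 5 against genes of the same class and 1 to 4 with a replicate left out (both chosen after seeing the data). By share of TPM, ribosomal protein genes took 1.54%, spike-in, phiX and tRNA rows 0.0323%, the 10 most abundant genes 71.9% and the 7SL genes 58.2%, short RNAs weighing more in TPM. Of 139 named genes, 105 moved by over 1 SD with read-derived TPM, mostly by a common scaling (104 of 106 at 1 TPM or more were lower, median ratio 0.376, and 22 moved once divided by it), and 24 with posterior mean TPM. Leading transcripts differed for 548 genes at 5 TPM or more, 72 at 50 TPM or more and 12 with shares over 0.6. Replicate 1 had the fewest counts, which limits low genes most there.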

Other observations

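The 5 gene groups below lie outside the fixed lists and, with the genes named, were chosen after the data were seen; no test was run on them. Of 16 complement genes, 10 reached 1 TPM in every library. The 3 C1q genes were abundant, with C1qb at 1007 ± 145, C1qc at 784 ± 121 and C1qa at 258 ± 49.8 TPM (SD, n = 3). The complement receptor gene C3ar1 held 244 ± 36.5 TPM and properdin, Cfp, 219 ± 52.0, while C1s1 held 0.050 ± 0.026 TPM and Cfi had 0 counts. All 14 inflammasome and cell death genes reached 1 TPM in every library. The membrane rupture gene Ninj1 held 147 ± 11.5 TPM, Casp1 79.8 ± 7.34, Gsdmd 51.7 ± 10.5 and Casp4 31.8 ± 3.89, while Nlrp3 and Nlrc4 held 9.45 ± 0.665 and 1.92 ± 0.150 TPM.

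Among sensors, 12 of 13 reached 1 TPM in every library. The endosomal receptor genes Tlr7, Tlr8, Tlr9 and Tlr13 held 72.0 ± 15.2, 59.5 ± 13.8, 55.1 ± 20.5 and 54.6 ± 9.92 TPM (SD, n = 3), and the surface receptor genes Tlr1 and Tlr2 held 60.1 ± 7.10 and 35.3 ± 3.53. Tlr5, which senses flagellin, held 0.047 ± 0.031 TPM. Of 10 chemokine receptor genes, 7 reached 1 TPM, with Cmklr1 at 25.5 ± 6.94 TPM. Among 10 iron handling genes, 9 reached 1 TPM. The transferrin receptor gene Tfrc held 56.5 ± 16.6 TPM, the iron exporter gene Slc40a1 25.2 ± 6.64 and ceruloplasmin, Cp, 33.4 ± 16.04, while Hamp had 0 counts.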
